A study of Gallus gallus with 8 samples.

How the data were processed

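Total RNA from livers of 21-day-old broilers, taken 2 h after LPS or buffer, was enriched for polyadenylated RNA, fragmented and divided into an input part and a part immunoprecipitated with an antibody against m6A. Per the labels' protocols, strand was marked with dUTP and libraries were sequenced from both ends on an Illumina instrument. The 8 libraries were placed into 4 groups of 2 (control input, LPS input, control IP, LPS IP) by their labelled treatment and library kind. Columns and lists marked as treated were taken as LPS, the only treatment the labels name. A non-specific antibody control that the protocol mentions was not analysed here.

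Per the submitters' processing notes, HISAT2, StringTie, HOMER and ChIPseeker were used, without stated roles or versions. The genome build, the peak caller and any filters are not given in the sources used here. The authors deposited FPKM values, 1 column for each input library, for 13427 Ensembl genes. FPKM are not counts, and no read totals were used here. For peaks, the authors deposited 1 list for each treatment, IP against input, with a fold enrichment (a ratio of IP to input) for each peak. A p-value for each peak is also deposited by the authors, and the values equal 10 to the power of the listed logarithm. Some peak p-values are listed as 0, which is below what a computer number can hold. Each peak came with its exon blocks, its strand and the authors' annotation to a 3′ UTR, 5′ UTR or exon. The lists hold 7814 and 5939 entries; 1 entry in each repeats another exactly and was dropped, leaving 7813 and 5938.

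Gene symbols are those of the table. Where it gave none, the RefSeq accession in the description, or a synonym, was looked up in a RefSeq table of another assembly (GRCg7b), used only for names. Of 1047 names in 33 gene lists, 755 matched a gene of the table. ALAS2, PC and TM7SF2 were left out of a list because the synonym led to another gene. IL1B and METTL3 were not analysed here.

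Depth was judged from FPKM under 0.1, where a gene with 1 read in each of a pair of libraries gives the ratio of their depths. Relative to control library 1, it was 0.858 for control library 2, 0.818 for LPS library 1 and 0.891 for LPS library 2, from 25, 20 and 23 genes at the most frequent step. FPKM sums were 539984 and 568721 in control and 547260 and 560738 in LPS libraries.

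Expression was compared with limma 3.58.1 in R 4.3.3, with a trended prior variance, on log2(FPKM + 1), for the 9484 genes with a mean of at least 1 FPKM over the 4 input libraries, 2 against 2. Calls needed a Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Standard errors are those of limma. Lists with at least 5 tested genes (32 of 33) were tested with camera at a preset correlation of 0.01, which compares a list with all other tested genes, so a list whose median lies between 0 and the shift of all genes can point up. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, stood beside it. Counts of members past the test are given over all tested genes and adjusted over the list alone.

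The lists cover m6A writers, erasers and readers; positive and negative acute phase proteins; cytokines; chemokines; Toll-like receptor and NF-kB signalling; interferon response; cytokine receptors and JAK-STAT feedback; immediate early genes; glucocorticoid response; cholesterol synthesis; fatty acid and triglyceride synthesis; fatty acid oxidation; gluconeogenesis and glycogen; drug and bile acid metabolism; oxidative stress and heme; heat shock and unfolded proteins; cell death; circadian clock; respiratory chain; proteasome and antigen presentation; and cell cycle. Marker lists cover hepatocytes, macrophages, heterophils, T and NK cells, B cells, erythrocytes, thrombocytes, endothelium, stellate cells and fibroblasts, bile duct cells, and carry-over of pancreas, gut and muscle. Some genes are in more than 1 list.

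The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes with a symbol whose LPS libraries both lay outside the control range, up to 3 called members of each list with the largest change, and a fixed set (METTL3, METTL14, WTAP, FTO, ALKBH5, YTHDF2, IL1B, IL6, TLR4, serum amyloid A, albumin). Where 5 or fewer members of a list went one way, all are named, apart from a few genes not reported here; those outside the rule, HMGCS1, the second CCL4 entry and avidin were chosen after their values were seen. Named peaks were the 5 of highest fold enrichment in each list, the 5 shared peaks with the largest difference each way, and peaks of the genes with the largest change and of the fixed set.

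Peaks were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was shared if its exon blocks overlapped a peak of the other list on the same strand by at least 1 base. Shares have Wilson 95% intervals, which cover counting error only. Carrying a peak was compared between called and other genes with 100000 draws of tested genes matched on 20 bins of mean expression, and genes are not independent replicates. Fisher's exact test, which ignores expression, and permutation tests of fold change by peak class, where classes depend on expression in each state, were planned and are not reported. Figures were drawn with matplotlib 3.10.9.

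The expression test was run on simulated data with the means and spread of the control and LPS input comparison (9484 genes). It recovered 24% of the 100 genes changed 2-fold and 95% of the 100 changed 4-fold, with 11 false calls among 130. Far fewer genes were changed there than were called in the data (3996). The Benjamini-Hochberg adjustment is harsher when few genes change, so recovery in the data can differ from these values. Detection of 2-fold changes was limited in that setting, and a gene without a call is not shown to be unchanged.

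Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, libraries scaled to equal medians, quantile normalization, equal FPKM sums, a minimum change of 2-fold, a prior variance without trend or robust, a replicate block, and each input library left out in turn. Without a library, its group has 1 left, which limma assumes to vary like the others. The spread of each gene then rests on the other group alone. Without an LPS library, adjusted p-values of many genes were far smaller than with every library kept. A pass with a library left out is therefore not taken as support. For peaks they were the part of each list with fold enrichment above its median, equal numbers of top peaks, peaks on numbered chromosomes, Z and W, an overlap of 50% of both peaks, sharing by gene, a peak in both lists, and genes of at least 5 FPKM. Gene lists, and peaks against calls, at equal medians, and draws matched on the higher treatment mean, were added after the data were seen. A test of IP over input for each gene, of the m6A sequence motif in peaks and a match on transcript length were not run.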

Results

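N6-methyladenosine (m6A) is a methyl mark on internal adenosines of messenger RNA, and lipopolysaccharide (LPS) is the outer membrane component of Gram-negative bacteria that sets off innate immune signalling. Livers came from 21-day-old broilers killed 2 h after an intraperitoneal injection of 1 mg/kg LPS, or of saline buffer as the control. Polyadenylated RNA was fragmented and sequenced before (input) and after immunoprecipitation with an antibody against m6A (IP). There were 8 libraries in 4 groups of 2: control input, LPS input, control IP and LPS IP. The comparisons ask how liver mRNA and its m6A peaks differed between the control and the LPS-treated state.

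Gene levels were read from the input libraries, as FPKM for 13427 genes. Read totals were not used here, so absolute depth is unknown. The step between low values gave depths relative to control library 1 of 0.858 for control library 2, 0.818 for LPS library 1 and 0.891 for LPS library 2. Across genes, the Spearman correlation was 0.965 between the control libraries, 0.975 between the LPS libraries and at most 0.850 between a control and an LPS library. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries.

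After 2 h of LPS, inflammatory gene lists rose in liver RNA and the lists of cholesterol and fatty acid synthesis fell. Of the 32 lists, 13 passed in camera with its preset correlation and 12 in fry, and 0 did in camera with an estimated correlation (smallest adjusted p = 0.184; 4 lists at unadjusted p under 0.05). The largest rise among genes with a symbol was that of SLC6A14, a transporter of neutral and cationic amino acids, from 3.71 ± 0.668 to 566 ± 135 FPKM (SD, n = 2; log2 fold change 6.90, SE 0.22, limma adjusted p = 2.62e-06). The transglutaminase TGM4 (log2 fold change 6.34), the siderophore-binding lipocalin Ex-FABP (6.28) and the inositol trisphosphate kinase ITPKB (6.23) followed. The largest fall was that of THRSPB, a regulator of lipid synthesis, from 1979 ± 152 to 11.99 ± 4.32 FPKM (log2 fold change −7.29, SE 0.24, adjusted p = 3.10e-06). CYP1A4 (−6.25) and CYP1A1 (−4.90), which oxidise foreign compounds, fell too.

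The other rises among the 10 largest of genes with a symbol were those of TNFRSF9, a costimulatory receptor (6.04), the chemokines CCL4 (5.98) and CCL20 (5.43), the inducible nitric oxide synthase INOS (5.97), the feedback inhibitor of cytokine signalling SOCS1 (5.33) and NOXO1, an organiser of NADPH oxidase (5.23). INOS went from 1.36 ± 0.703 to 144 ± 0.573 FPKM. A second entry named CCL4 rose by 4.04. Further falls among the 10 largest of genes with a symbol were those of THRSP (−6.96), the hexokinase-like HKDC1 (−5.30), the glycogen-targeting phosphatase subunit PPP1R3B (−5.25), the acetoacetyl-CoA synthetase AACS (−4.78), the kinase CDK18 (−4.66) and CYP7A1, the rate-limiting enzyme of bile acid synthesis (−4.64). Another entry named THRSP fell by 4.31 on the log2 scale, from 5430 ± 686 to 289 ± 141 FPKM. The entries named THRSP or THRSPB, the CCL4 entries, and CYP1A1 with CYP1A4 are close relatives, and reads split between them make their separate values uncertain. Both LPS libraries lay outside the range of both control libraries for each of these genes.

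**Figure D1:**
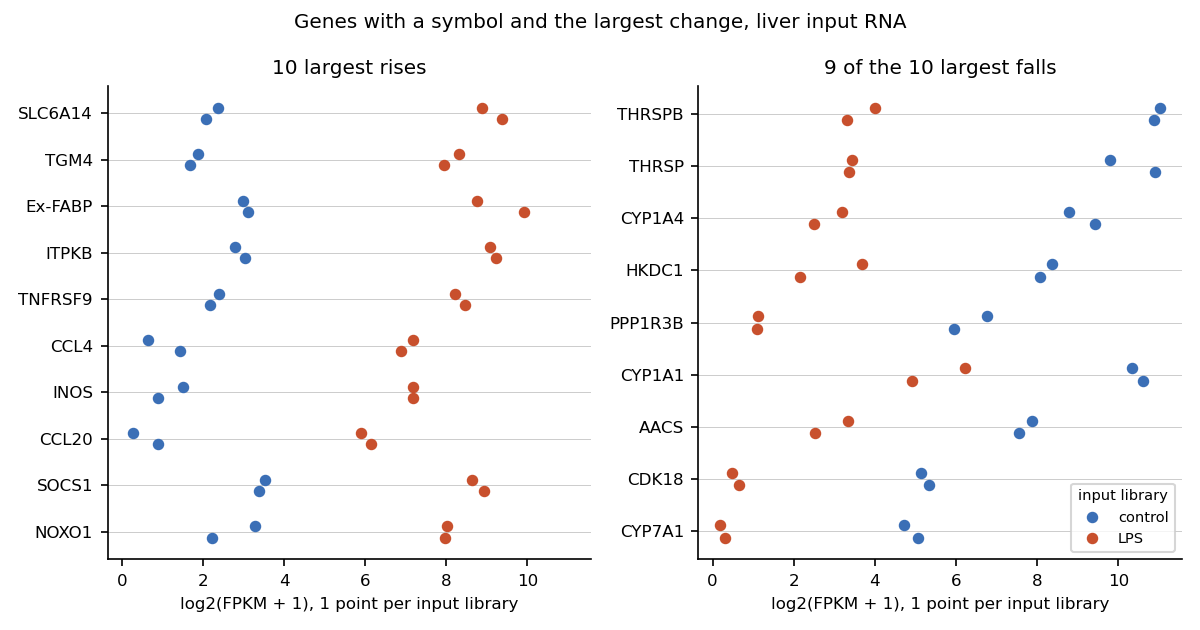
Expression, among genes with a symbol, of the 10 with the largest rise (left) and 9 of the 10 with the largest fall (right), as log2(FPKM + 1) on the horizontal axis, with 1 point for each of the 4 input libraries. SLC6A14 had a mean of 3.71 FPKM in control and 566 FPKM in LPS liver, and THRSPB 1979 and 11.99 FPKM.

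In all, 1014 of 9484 tested genes rose and 2982 fell (limma, Benjamini-Hochberg adjusted p under 0.05), so 74.6% of the calls were falls. The median log2 fold change of all tested genes was −0.34. With libraries scaled to equal medians it was −0.07, and 1341 genes were higher and 1594 lower, 54.3% of the calls. Counts for each gene group are therefore given on both scales, and a fold change is to be read against the shift of −0.34. With a minimum change of 2-fold, 674 genes were higher and 1365 lower.

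Acute phase proteins, many of which the liver secretes into plasma during inflammation, rose as a group. Serum amyloid A went from 309.8 ± 189.9 to 18939.6 ± 2572 FPKM (SD, n = 2; log2 fold change 6.07, SE 0.39, limma adjusted p = 3.88e-05). The pantetheinase VNN1 (4.45), the metallothionein MT1 (3.78) and Ex-FABP (6.28) also rose. Serum amyloid A and avidin were not matched to a member of the list, so its counts and tests leave them out. Of the 16 positive acute phase genes tested in the list, 12 rose, 0 fell and 4 did not pass, with 12 and 0 adjusted over the list alone, 12 and 0 at unadjusted limma p under 0.05, and 13 and 0 at equal medians. The camera adjusted p was 1.76e-11, and the adjusted p = 0.184 with an estimated correlation.

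Secreted proteins that usually decline in inflammation were mixed. IGFALS, which carries insulin-like growth factors, fell by 1.89 and the carrier protein AHSG by 1.24 on the log2 scale, while the plasmin inhibitor SERPINF2 rose (1.29). Albumin (ALB), the main plasma protein, was at 19737 ± 4522 FPKM in control and 22954 ± 523 in LPS liver (log2 fold change 0.24, limma adjusted p = 0.427). Of the 19 such genes tested, 1 rose, 4 fell and 14 did not pass (1 and 3 adjusted over the list alone), against 4 higher and 2 lower at equal medians, where the balance turned. The other fallen members lost their calls at equal medians: TTR had an adjusted p = 0.114 there, 0.192 without control library 2 and 0.211 without LPS library 2, and apoAIV 0.110 there, 0.0515 without control library 1, 0.0548 without LPS library 1 and 0.0901 without LPS library 2. The list median was −0.12 and camera pointed up, relative to all other genes, without passing (adjusted p = 0.502).

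Cytokine and chemokine genes had the highest median log2 fold changes of the lists (2.24 and 2.23). IL1R2, a decoy receptor for interleukin 1 (4.74), the inflammasome product IL18 (3.66) and the interleukin 33 receptor IL1RL1 (3.50) rose. Of the 15 cytokine and cytokine receptor genes tested, 13 rose, 1 fell and 1 did not pass (13 and 1 adjusted over the list alone, 13 and 1 at equal medians). IL15, which sustains natural killer cells, was the fallen member (−1.15). The list passed upward (camera adjusted p = 1.28e-12), and the adjusted p = 0.184 with an estimated correlation. IL6 was below the filter, at 0.0614 FPKM in control library 1, listed at 0 in control library 2, and at 1.27 and 2.07 FPKM in the LPS libraries. IL1B was not analysed here.

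The leukocyte attractants CCL20 (5.43), CCL1 (4.70) and CCL19 (4.37) rose. Of the 10 chemokine genes tested, 6 rose, 2 fell and 2 did not pass (7 and 2 adjusted over the list alone, 7 and 0 at equal medians). Chemokines passed upward as a list (camera adjusted p = 4.33e-06), and the adjusted p = 0.425 with an estimated correlation. The fallen members were CCLI10, whose adjusted p rose to 0.124 at equal medians, 0.167 without control library 2 and 0.0586 without LPS library 1, and CXCL12, with 0.0988 at equal medians, 0.123 without control library 2 and 0.155 without LPS library 2.

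Genes of the Toll-like receptor and NF-kB pathway, and of the interferon response, rose as lists. The NF-kB inhibitors NFKBIA (4.06) and TNIP2 (4.87), which feed back on the pathway, rose, and TLR4, the receptor for LPS itself, fell by 1.12 on the log2 scale, from 2.25 ± 0.257 to 0.495 ± 0.00435 FPKM (SD, n = 2; limma adjusted p = 0.00617). Of the 34 Toll-like receptor and NF-kB genes tested, 20 rose, 4 fell and 10 did not pass (21 and 6 adjusted over the list alone, 22 and 3 at equal medians). As a list these genes passed upward (camera adjusted p = 2.94e-11), and the adjusted p = 0.211 with an estimated correlation. Besides TLR4, the adaptor TICAM1 (−1.06), the kinase IRAK4 (−0.93) and TLR5, the flagellin receptor, were lower. The TLR5 call ended at equal medians (adjusted p = 0.107), without control library 1 (0.135), without LPS library 1 (0.0577) and without LPS library 2 (0.121).

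Interferon-induced antiviral genes included RSAD2 (3.93) and OAS*A (3.78), and the checkpoint ligand CD274 rose by 3.05. Of the 34 interferon response genes tested, 25 rose, 1 fell (TDRD7) and 8 did not pass (28 and 1 adjusted over the list alone, 29 and 1 at equal medians). Of all lists this had the smallest camera adjusted p, 1.90e-20, and the adjusted p = 0.326 with an estimated correlation.

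Feedback regulators of cytokine receptors included SOCS1 (5.33), SOCS3 and the soluble interleukin 22 binding protein IL22RA2 (3.93). Of the 26 genes tested for cytokine receptors and JAK-STAT feedback, 16 rose, 2 fell and 8 did not pass (16 and 3 adjusted over the list alone, 17 and 1 at equal medians). The camera adjusted p was 1.20e-10, and the adjusted p = 0.184 with an estimated correlation. The fallen members were IL2RG (−0.79; adjusted p = 0.0853 at equal medians) and SOCS2 (−0.96; adjusted p = 0.0611 without LPS library 1).

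Genes of cell death rose, among them the decoy receptor TNFRSF6B (4.66), the necroptosis effector MLKL (4.53) and the death receptor FAS (2.34). Of the 24 tested, 11 rose, 1 fell and 12 did not pass (11 and 1 adjusted over the list alone, 15 and 0 at equal medians). Cell death genes passed upward (camera adjusted p = 3.76e-08), and the adjusted p = 0.326 with an estimated correlation. The fallen member was the adaptor FADD (−0.87), with an adjusted p = 0.0562 at equal medians and 0.0564 without LPS library 2.

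Immediate early genes, which are switched on early after a stimulus, were split. ATF3 (3.66), FOSL2 (2.71) and BTG2 (2.49) rose, and EGR1 (−1.91), gadd45 (−1.31), MYC (−1.09) and FOS (−0.95) fell. Of the 19 tested, 6 rose, 5 fell and 8 did not pass (7 and 5 adjusted over the list alone, 9 and 4 at equal medians). KLF4 was the remaining fallen member, with an adjusted p = 0.131 at equal medians, 0.133 without control library 2, 0.0719 without LPS library 1 and 0.221 without LPS library 2. The list passed upward (camera adjusted p = 0.0259), with an adjusted p = 0.535 with an estimated correlation, and did not pass in fry (0.182), at equal medians (0.0651), without control library 1 (0.0732) or without LPS library 2 (0.0748).

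Of the 14 genes tested for the glucocorticoid response, 4 rose, 2 fell and 8 did not pass (6 and 2 adjusted over the list alone, 6 and 2 at equal medians). The risen members were PDK4, which restrains pyruvate oxidation (4.78), ZBTB16 (3.29), the metallothionein MT4 (3.00) and the receptor chaperone FKBP51 (2.02). ANGPTL4, an inhibitor of lipoprotein lipase, fell by 3.96 and the transcription factor KLF9 by 1.25 on the log2 scale, the latter with an adjusted p = 0.0842 without control library 2. The camera adjusted p was 0.00192, and the adjusted p = 0.326 with an estimated correlation.

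Lipid synthesis fell on both scales. Among cholesterol genes, the sterol carrier STARD4 (−3.36), the isomerase EBP (−2.99) and squalene synthase FDFT1 (−2.77) fell. HMGCS1, which makes the mevalonate precursor in the cytosol, was the only tested member of the list that rose, from 330 ± 41.7 to 1367 ± 81.2 FPKM (SD, n = 2; log2 fold change 2.05, SE 0.18, limma adjusted p = 1.61e-04). Of the 22 tested, 1 rose, 18 fell and 3 did not pass (1 and 18 adjusted over the list alone, 1 and 18 at equal medians). The members without a call were ACAT2, GGPS1 and SREBF2. Cholesterol synthesis passed downward (camera adjusted p = 4.42e-04), but not in fry (0.0728), and the adjusted p = 0.535 with an estimated correlation.

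Fatty acid and triglyceride synthesis fell likewise. THRSPB (−7.29) and GPAM, which adds the first fatty acid to glycerol phosphate (−4.44), fell, and the phosphatidate phosphatases Lpin1 (1.69) and LPIN2 (1.51) rose. Of the 25 tested, 2 rose, 19 fell and 4 did not pass (2 and 19 adjusted over the list alone, 2 and 17 at equal medians). Fatty acid synthesis passed downward (camera adjusted p = 2.06e-04), and the adjusted p = 0.535 with an estimated correlation.

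Fatty acid oxidation and ketogenesis had few calls. PDK4 rose (4.78), as did the carnitine acyltransferases CPT1A (1.57; adjusted p = 0.0604 without control library 2) and CROT (1.06; adjusted p = 0.0509 without control library 2). Of the 27 tested, 3 rose, 3 fell and 21 did not pass (3 and 3 adjusted over the list alone, 6 and 1 at equal medians; camera adjusted p = 0.0591 as deposited, 0.0246 at equal medians and 0.0143 without LPS library 2, upward, against 0.331, 0.116 and 0.0568 without LPS library 1, control library 1 and control library 2). Among the fallen members, ACOX2 and CPT2 lost their calls at equal medians (adjusted p = 0.0720 and 0.122). They also lost them without control library 1 (0.0562 and 0.0653) and without LPS library 2 (0.0643 and 0.0638).

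PPP1R3B (−5.25) and PPP1R3C (−4.60), which target a phosphatase to glycogen, fell, and the glycolytic regulator PFKFB3 rose by 2.93. Of the 18 genes tested for gluconeogenesis and glycogen, 3 rose, 6 fell and 9 did not pass (3 and 8 adjusted over the list alone, 3 and 4 at equal medians; camera adjusted p = 0.707, upward although the median was −0.02). PDK4 (4.78) and the transaminase GPT2 (0.90; adjusted p = 0.0939 without control library 2) were the other risen members.

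Enzymes of drug and bile acid metabolism included the largest falls of CYP1A4 (−6.25), CYP1A1 (−4.90) and CYP7A1 (−4.64). Of the 21 tested, 3 rose, 12 fell and 6 did not pass (3 and 12 adjusted over the list alone, 3 and 7 at equal medians). Those that rose were the cytochromes cyp3A37 (2.17) and CYP2D6 (1.43) and FXR, the bile acid receptor (1.37). The list did not pass (camera adjusted p = 0.177, downward). With 1 library left out it passed only where an LPS library was dropped, and such a pass is not taken as support.

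**Figure D2:**
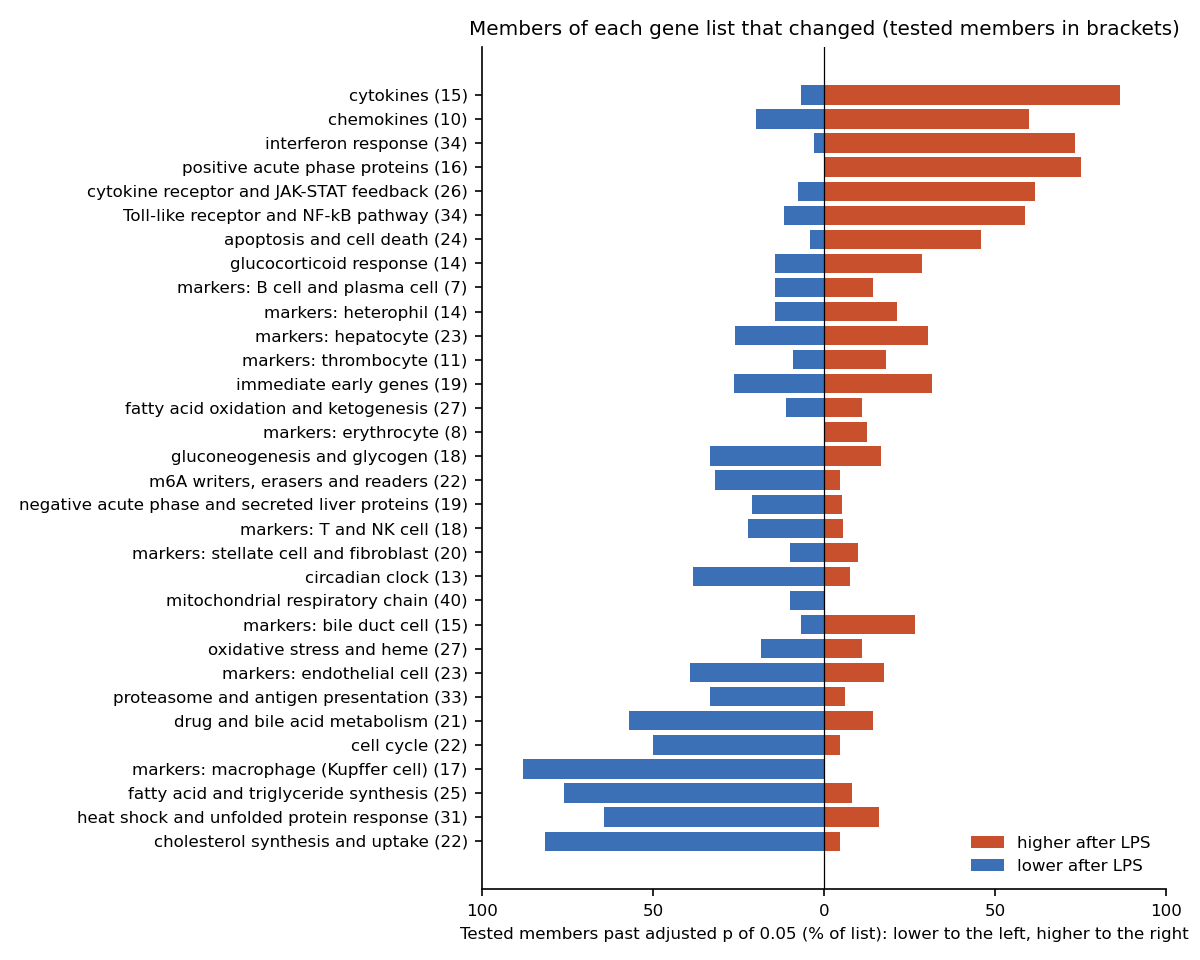
Share of the tested members of each gene list that were higher (to the right) or lower (to the left) after LPS at an adjusted p under 0.05, as a percentage of the list, on the FPKM scale as deposited. Lists run from the highest median log2 fold change at the top to the lowest at the bottom; at equal medians the balance turns from lower to higher for the m6A list (1 and 7 to 2 and 1) and for the proteasome list (2 and 11 to 5 and 1), among others given in the text.

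The m6A machinery itself changed little compared with the inflammatory genes. Among writers, METTL14, a core subunit of the methyltransferase, was at 4.14 ± 0.467 FPKM in control and 5.29 ± 0.506 in LPS liver (SD, n = 2; log2 fold change 0.29, limma adjusted p = 0.275), and WTAP, its adaptor, at 17.5 ± 1.12 and 25.1 ± 0.523 FPKM (0.50, adjusted p = 0.0512, against 0.0107 at equal medians). The reader YTHDF2 was at 16.7 ± 1.68 and 15.6 ± 0.204 FPKM (−0.09, adjusted p = 0.692). The eraser ALKBH5 fell by 0.74 on the log2 scale (adjusted p = 0.0288), a call that ended at equal medians (−0.44, adjusted p = 0.164), without control library 1 (0.0543), without control library 2 (0.113) and without LPS library 2 (0.194). The eraser FTO was below the filter, at 0.175 ± 0.0311 FPKM in control and 0.0409 ± 0.0338 FPKM in LPS liver, and METTL3 was not analysed here.

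Of the 22 writers, erasers and readers tested, 1 rose, 7 fell and 14 did not pass (1 and 5 adjusted over the list alone), against 2 higher and 1 lower at equal medians, where the balance turned. The list median was −0.12, camera pointed up relative to all other genes without passing (adjusted p = 0.768), and fry, which tests the list alone, pointed down (adjusted p = 0.0306). The reader IGF2BP2 rose (0.79; adjusted p = 0.0666 without LPS library 2) and the ribosomal RNA methyltransferase METTL5 fell (−0.98; adjusted p = 0.0518 without LPS library 1).

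Among cell type markers, those of Kupffer cells, the resident macrophages of liver, fell on both scales. They included the growth factor receptor CSF1R (−1.51), the metal transporter SLC11A1 and the complement subunit C1QB (−1.44). Of the 17 macrophage markers tested, 0 rose, 15 fell and 2 (Ii and Nox2) did not pass, with 0 and 16 adjusted over the list alone, 0 and 16 at unadjusted limma p under 0.05, and 0 and 11 at equal medians. Macrophage markers passed downward (camera adjusted p = 2.84e-04), and the adjusted p = 0.326 with an estimated correlation. Of the 14 markers tested for heterophils, the avian counterpart of neutrophils, 3 rose, 2 fell and 9 did not pass (3 and 2 adjusted over the list alone, 4 and 1 at equal medians). IL1R2 (4.74), which is also in the cytokine list, the protease MMP9 (1.54) and PTAFR (1.51) rose, and RSFR fell (−1.18). The heterophil list passed upward (camera adjusted p = 0.0245), with an adjusted p = 0.535 with an estimated correlation, and did not pass in fry (0.377), at equal medians (0.0686), without control library 1 (0.0819) or without LPS library 1 (0.227).

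Hepatocyte markers went both ways: the liver transcription factor HNF4alpha fell (−3.78) and the arginase ARG2 rose (2.76). Of the 23 tested, 7 rose, 6 fell and 10 did not pass (7 and 6 adjusted over the list alone, 8 and 5 at equal medians; camera adjusted p = 0.0503, and 0.0340 without control library 2). Endothelial markers did so too, with the leukocyte adhesion molecules SELE (2.98) and VCAM1 (1.75) and the growth factor receptor FLT1 (1.06) higher and the receptor TIE1 (−1.86) lower. ESAM was higher as well (0.70; adjusted p = 0.0729 without control library 1 and 0.0957 without LPS library 2). Of the 23 endothelial markers tested, 4 rose, 9 fell and 10 did not pass (5 and 9 adjusted over the list alone, 5 and 5 at equal medians; camera adjusted p = 0.707, upward although the median was −0.30).

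The remaining cell type lists did not pass with all libraries. Among the 15 bile duct markers tested, 4 rose, 1 fell and 10 did not pass (4 and 1 adjusted over the list alone, 5 and 0 at equal medians; camera adjusted p = 0.127, upward although the median was −0.27, and 0.0216 without LPS library 1 and 0.0175 without control library 2). SPP1 (2.95), EPCAM (1.38), AQP1 (0.95) and ELF3 (1.23; adjusted p = 0.134 without control library 2) rose, and the call of Sox9 (−1.01) ended at equal medians (adjusted p = 0.0998), without control library 2 (0.183) and without LPS library 1 (0.137). Among the 20 stellate cell and fibroblast markers, 2 rose, 2 fell and 16 did not pass (2 and 2 adjusted over the list alone, 5 and 2 at equal medians; camera adjusted p = 0.418, upward although the median was −0.25). DES rose (1.42), LRAT (−1.13) and LUM fell, and OSF-2 (1.03) had an adjusted p = 0.0547 without control library 1, 0.1196 without control library 2 and 0.196 without LPS library 1.

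Among the 18 T and NK cell markers, 1 rose, 4 fell and 13 did not pass (1 and 1 adjusted over the list alone), against 3 higher and 1 lower at equal medians, where the balance turned (camera adjusted p = 0.567, upward although the median was −0.20). IL7R rose (1.46) and TCF1 fell (−1.74). LCK, CD28 and CD247 fell as well, but not at equal medians (adjusted p = 0.162, 0.0652 and 0.200). Without control library 2 their adjusted p-values were 0.0627, 0.111 and 0.122. LCK and CD247 also lost their calls without control library 1 (0.108 and 0.0653) and LPS library 1 (0.283 and 0.309), and CD28 and CD247 without LPS library 2 (0.0677 and 0.0683).

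Among the 7 B cell markers, 1 rose (CD72, 2.70), 1 fell (BLK) and 5 did not pass (1 and 0 adjusted over the list alone, 1 and 0 at equal medians; camera adjusted p = 0.123). The BLK call ended at equal medians (adjusted p = 0.126), and without control library 1 (0.0966), control library 2 (0.0718), LPS library 1 (0.195) or LPS library 2 (0.145). Among the 11 thrombocyte markers, 2 rose (k60, 2.10, and ITGB3, 1.36), 1 fell (TUBB1) and 8 did not pass (2 and 0 adjusted over the list alone, 3 and 0 at equal medians; camera adjusted p = 0.0539, and 0.0340 without control library 2). The TUBB1 call ended at equal medians (adjusted p = 0.140), and without control library 1 (0.117), control library 2 (0.0925) or LPS library 1 (0.322). Among the 8 erythrocyte markers, 1 rose (the transferrin receptor TFRC, 1.41), 0 fell and 7 did not pass, with 1 and 0 adjusted over the list alone, 1 and 1 at unadjusted limma p under 0.05, and 1 and 0 at equal medians (camera adjusted p = 0.168, upward although the median was −0.01). Only 2 markers of pancreas, gut and muscle could be tested, too few for camera; 0 rose and 1 fell, with 0 and 1 adjusted over the list alone, 0 and 1 at unadjusted limma p under 0.05 and 0 and 0 at equal medians. That gene was ACTA1, whose call ended at equal medians (adjusted p = 0.160), and without control library 1 (0.0989), control library 2 (0.149) or LPS library 1 (0.353).

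Liver mRNA carried m6A peaks in 5387 genes over both states, and most peaks found after LPS were also found in control. The control list held 7813 peaks in 5048 genes and the LPS list 5938 peaks in 3992 genes. The strongest control peak was in the 3′ UTR of the major histocompatibility gene BF1, on chromosome 16 from base 71990 to 73366, with a fold enrichment of IP over input of 2300, and the BF1 peak of the LPS list reached 1440. The tight junction gene CLDN2 (1410; chromosome 4, 10921953 to 10922848, 3′ UTR), IGSF9 (1240; chromosome 25, 1691235 to 1692904, exon 17 of 20), PCYOX1L (1120; chromosome 13, 7850497 to 7851238, 3′ UTR) and RNF121 (973; chromosome 1, 193350970 to 193351817, 3′ UTR) followed in control. The LPS list was led by VWCE (2240; chromosome 5, 410198 to 411096, 3′ UTR), with SF3A2 (937; chromosome 28, 1962152 to 1962783, 3′ UTR), the elastin gene ELN (772; chromosome 19, 804002 to 804855, 3′ UTR) and C6orf132 (748; chromosome 26, 3144909 to 3147043, exon 3 of 6) after BF1.

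Fold enrichments and p-values of peaks are the authors' own. There is 1 list for each treatment and no list for each library, so peak values have no replicate, and intervals on differences between the lists leave out the spread between libraries. The genome build of the coordinates is not given in the sources used here.

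Most peaks were annotated to a 3′ UTR or to an exon outside the UTR classes. In control, 3531 peaks (45.2%, Wilson 95% interval 44.1 to 46.3%) were annotated to a 3′ UTR, 599 (7.67%, 7.10 to 8.28%) to a 5′ UTR and 3683 (47.1%, 46.0 to 48.2%) to another exon. After LPS the numbers were 2505 (42.2%, 40.9 to 43.4%), 421 (7.09%, 6.46 to 7.77%) and 3012 (50.7%, 49.5 to 52.0%). The 3′ UTR share was lower in the LPS list (difference −3.01 points, 95% interval −4.68 to −1.34). These intervals cover counting error only. In the upper part of each list by fold enrichment the difference was −3.47 points. It was −5.39 points for as many of the top control peaks as the LPS list holds, a choice that raises the control share because peaks of higher fold lie more often in 3′ UTRs. Of the exon peaks, 25.4% in control and 26.0% in LPS lay in the last exon. The median exonic length was 241 bases in control and 237 in LPS, and the median fold enrichment 5.51 and 4.99. The upper quartile of length was 389 bases in control and 331 in LPS. Overlapping peaks could differ in class: the METTL14 peak was annotated to a 3′ UTR in control and to an exon in LPS. The other way, an exon peak of ITPKB in control overlapped a 3′ UTR peak in LPS. The difference in 3′ UTR share is therefore not shown to be a shift of m6A along transcripts.

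By position, 5006 control peaks (64.1%, 63.0 to 65.1%) overlapped an LPS peak on the same strand by at least 1 base, and 5204 LPS peaks (87.6%, 86.8 to 88.5%) overlapped a control peak. The other 2807 control peaks and 734 LPS peaks were in 1 list only. By gene, 3653 had a peak in both lists, 1395 in control only and 339 in LPS only. Across 4925 matched pairs of peaks, fold enrichments ranked alike (Spearman correlation 0.863 across pairs, which are not independent replicates), 85.7% of pairs lay within 2-fold, and 32.2% had the higher value in the LPS list (median log2 ratio −0.25).

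**Figure D3:**
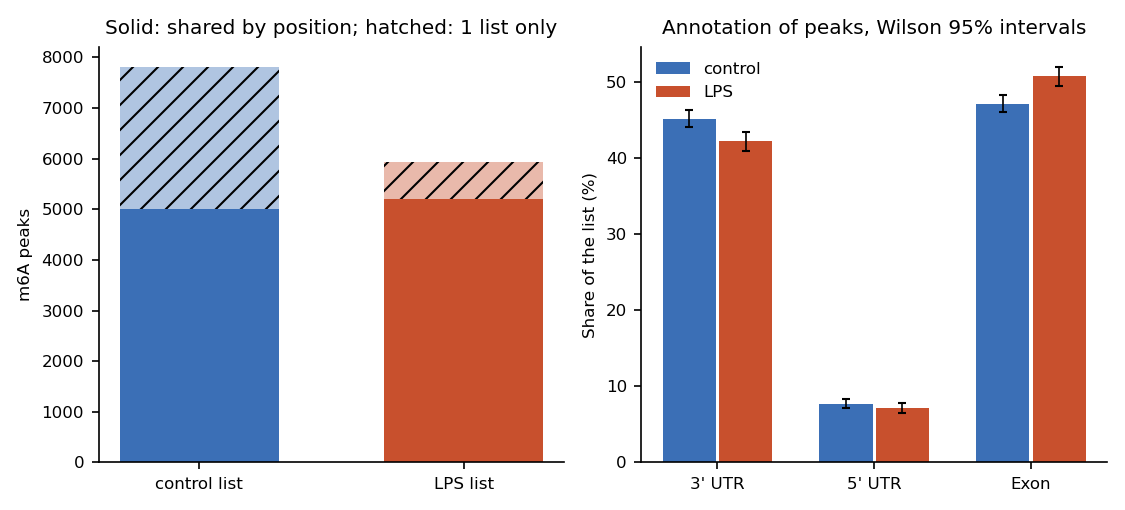
Left, number of m6A peaks in the control and the LPS list, with peaks that overlap a peak of the other list in solid colour (5006 and 5204) and peaks found in 1 list only hatched (2807 and 734). Right, share of each list annotated to 3′ UTR, 5′ UTR or another exon, in percent, with Wilson 95% intervals that cover counting error only; 3′ UTR peaks made up 45.2% of the control and 42.2% of the LPS list.

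Among shared peaks, side by side and untested, the largest differences toward control were in SDK2 (fold enrichment 471 in control and 17.1 in LPS; last exon, chromosome 18), AP1B1 (611 and 26.4; 3′ UTR, chromosome 15), PLPPR3 (80.6 and 4.49; last exon, chromosome 28), TIMMDC1 (112 and 7.41; 3′ UTR, chromosome 1) and CLDN2 (1410 and 119). The largest toward LPS were in RAB44 (3.50 and 57.2, 5′ end, chromosome 26), SPSB3 (4.71 and 32.4, 3′ UTR, chromosome 14), NES (13.4 and 83.1, last exon, chromosome 25), MTSS1L (28.3 and 170, last exon, chromosome 11) and SLU7 (11 and 60, 5′ UTR, chromosome 13). Paired peaks overlap but are not the same interval. The SDK2 peak spanned 241 bases in control and 61 in LPS, and the RAB44 peak 180 and 269.

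Among genes of the m6A machinery, METTL14, WTAP, YTHDF2 and ALKBH5 carried peaks in both lists and FTO in neither. METTL14 had 1 peak near its 3′ end in each, from base 54395202 to 54395501 of chromosome 4 in control, with fold enrichments of 18.1 in control and 6.04 in LPS. WTAP had 2 peaks in each list and YTHDF2 had 3, the highest of YTHDF2 at 24.2 and 11.9 in its first exon. ALKBH5 had 1 peak at its 5′ end (8.55 and 6.20) and 1 in its 3′ UTR (3.99 and 2.44) in each list. ALB had 1 peak in its 3′ UTR at the same coordinates in both lists, with 26.6 and 27.7.

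Several genes with the largest changes had a peak only in the list of the state with the higher expression. Of the 10 largest rises among genes with a symbol, SOCS1 and ITPKB had a peak in both lists, TGM4, Ex-FABP and NOXO1 in LPS only, and 5 in neither. The TGM4 peak in the 3′ UTR, on chromosome 2 from base 43743131 to 43743460, had a fold enrichment of 8.90. Of the 10 largest such falls, CYP1A1 and PPP1R3B had a peak in both lists, THRSPB, CYP1A4, HKDC1, CDK18 and CYP7A1 in control only, and 3 in neither. The CYP1A4 peak in the 3′ UTR, on chromosome 10 from base 1946340 to 1946669, had a fold enrichment of 19.3. SOCS1 had 1 peak in its 3′ UTR in each list, with 3.89 in control and 5.66 in LPS.

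Tested genes were also grouped by the list that held their peak. The 309 genes with a peak in LPS only had a median log2 fold change of 0.61, and 147 of them rose and 20 fell. The 1215 genes with a peak in control only had a median of −0.65, and 16 rose and 636 fell. The 3578 genes with a peak in both lists had −0.28 and the 4382 without a peak −0.33. Against genes without a peak the differences were 0.95, −0.32 and 0.05 in turn. Whether a peak can be called depends in part on expression in each state, so these differences are described and no p-value is given.

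**Figure D4:**
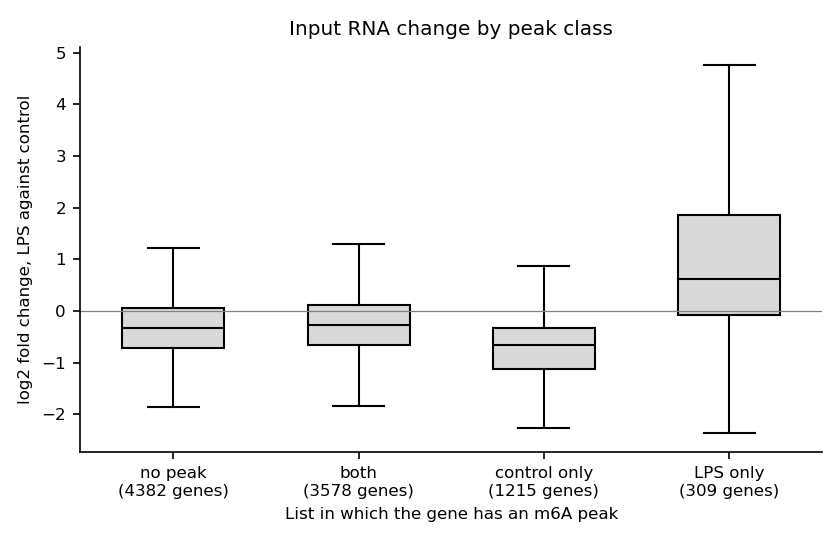
Log2 fold change of input RNA, LPS against control, for tested genes grouped by the list in which they have an m6A peak, with the number of genes under each box. Boxes span the quartiles with the median as a line, whiskers span the genes beyond them without outlying values; medians were −0.33 without a peak, −0.28 with a peak in both lists, −0.65 in control only and 0.61 in LPS only.

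Of the 1014 risen genes, 607 (59.9%) carried a peak in either list, and of the 2982 fallen genes 1707 (57.2%), against 2788 of 5488 genes without a call (50.8%). Draws matched on the higher of the treatment means gave 59.1% and 57.2%, so risen and fallen genes differed from them by 0.799 and 0.0204 points (two-sided permutation p = 0.577 and 0.981, both 0.981 after adjustment over 2 tests). This match was chosen after the results were seen. Draws matched on the mean over both treatments, as planned, gave differences of 3.998 and 2.02 points (permutation p = 0.00433 and 0.00514, both 0.00514 after adjustment), and 3.14 and 4.38 points for calls at equal medians. That match favours changed genes, which reach a higher level in one state than unchanged genes of the same mean, so no excess of peaks is claimed for them.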

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

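Of the alternatives given here, tests of gene lists, and of peaks against calls, at equal medians, and draws matched on the higher treatment mean, were chosen after the results were seen. Calls of genes numbered 2906 to 3360 with 1 library left out, and 2835 to 4057 under the other settings that kept every fold size and had no replicate block; with a minimum change of 2-fold they were 2039 (674 higher, 1365 lower). Scaling to equal medians moved the falls from 2982 to 1594, and quantile normalization to 1505, because both remove most of the median shift of all genes; 2608 and 2512 of the original calls remained. Among genes named by the rule, with HMGCS1 and avidin, none reversed under these settings. Of the 107 of them with a call, 90 kept it in every setting that tested them, other than the 2-fold one. At 5 FPKM or more, 94 of 111 were tested. Called list members named outside the rule are not in this count, and several lost their calls, as given with their lists. For lists, 13 passed in camera and 12 to 17 with 1 library left out; with an estimated correlation 0 passed (4 at unadjusted p under 0.05), and fry called 12, of which 10 were shared. The m6A list reversed, with fry, which does not compare it with other genes, pointing down (adjusted p = 0.0306). The replicate block gave 4221 calls of genes and 15 of lists, the added ones being cell cycle and heat shock. It changed no call among the 111 genes counted above. Deviations of same-numbered libraries correlated at 0.0292, so little common deviation was seen. The labels do not say what else these libraries share. For peaks, the upper part of each list by fold enrichment held 3906 control peaks in 3116 genes and 2969 LPS peaks in 2401 genes. With equal numbers of peaks the 3′ UTR difference went to −5.39 points. The shared share of control peaks was 52.5% and of LPS peaks 69.0% with an overlap of 50%, 77.7% and 93.1% by gene, and 85.5% of LPS peaks in the upper part. Against genes matched on the mean, the difference at 5 FPKM or more was 5.06 points for risen genes (permutation p = 0.00161) and 1.30 for fallen genes, which did not pass (0.128). For a peak in both lists, which depends on expression in each state, it was 3.32 (0.0160) and −4.14 points (1e-05, the smallest the draws can give). Matched on the higher treatment mean, the differences were 0.799 points for risen and 0.0204 for fallen genes. Why an overlap of 50% or sharing by gene moved the peak values was not tested. The IP over input test, the motif test and the match on length were not run. Unknown read totals limit what missing peaks and low genes can show.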

Other observations

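The separate tests of lost and of gained peaks, and the reading of the turnover bound by its interval, were chosen after the results were seen, and the dilution test was added after the other tests but before its own value was computed. The chaperones HSP90AA1 (−2.95), HSPA8 (−2.64) and HSP90AB1 (−2.38), which fold client proteins in the cytosol, fell, HSPA8 going from 1544 ± 6.01 to 250.2 ± 51.8 FPKM (SD, n = 2; limma adjusted p = 7.37e-05). Of the 31 heat shock and unfolded protein genes tested, 5 rose, 20 fell and 6 did not pass (5 and 20 adjusted over the list alone, 5 and 16 at equal medians). The list did not pass as deposited (camera adjusted p = 0.0505, downward; fry 0.0593), with an adjusted p = 0.780 with an estimated correlation. It passed downward at equal medians (0.0152). With 1 library left out it passed except without control library 1, and such a pass is not taken as support. The splicing target and transcription factor XBP1 rose (0.95). HSPB1 (0.99), HSPH1 (0.77), BAG3 (0.69) and CHAC1 (1.38) rose as well, calls that ended without LPS library 1 (adjusted p = 0.0980, 0.0705, 0.154 and 0.0588). Those of HSPB1 and CHAC1 also ended without control library 1 (0.0874 and 0.190), and those of HSPH1 and BAG3 without control library 2 (0.0618 and 0.0939).

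The mitotic checkpoint kinase BUB1 (−3.62) and the replication helicase subunits MCM5 (−3.14) and MCM3 (−3.06) fell. Of the 22 cell cycle genes tested, 1 rose (CDK1, 0.93), 11 fell and 10 did not pass (1 and 11 adjusted over the list alone, 2 and 10 at equal medians). The list did not pass (camera adjusted p = 0.0548), with an adjusted p = 0.751 with an estimated correlation. It passed downward in fry (0.0497) and at equal medians (0.0132). With 1 library left out it passed except without control library 2, and such a pass is not taken as support. In heme and redox metabolism, ALAS1, the first enzyme of heme synthesis, fell by 3.32, and FTD (−1.16) and GCLM (−1.06) fell, while INOS (5.97) and HMOX1, which breaks heme down (1.47), rose. PRDX1 and NQO2 fell but not at equal medians (adjusted p = 0.0910 and 0.125), NQO2 also not without control library 2 (0.0874), LPS library 1 (0.0524) or LPS library 2 (0.200). MAFF rose (0.60), a call that ended without control library 1 (0.0860), LPS library 1 (0.131) or LPS library 2 (0.114). Of the 27 oxidative stress and heme genes tested, 3 rose, 5 fell and 19 did not pass (3 and 5 adjusted over the list alone, 4 and 3 at equal medians, where the balance turned; camera adjusted p = 0.761, upward although the median was −0.29).

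Clock repressors CRY2 (−1.40) and PER3 (−1.04) fell. TEF fell too (−1.25; adjusted p = 0.0557 without control library 2), and so did CRY1 and ARNTL2, which lost their calls at equal medians (adjusted p = 0.154 and 0.161), without control library 1 (0.0837 and 0.162), LPS library 1 (0.0812 and 0.155) and LPS library 2 (0.0600 and 0.138). BHLHE40 rose (1.30; adjusted p = 0.205 without control library 2 and 0.0810 without LPS library 2). Of the 13 clock genes tested, 1 rose, 5 fell and 7 did not pass (2 and 5 adjusted over the list alone, 3 and 3 at equal medians; camera adjusted p = 0.897, upward although the median was −0.26). Of the 33 proteasome and antigen presentation genes, 2 rose, 11 fell and 20 did not pass (2 and 10 adjusted over the list alone), against 5 higher and 1 lower at equal medians, where the balance turned (camera adjusted p = 0.709). The peptide transporters TAP2 and TAP1 (0.97) rose and the proteasome subunit PSMD4 fell (−0.89). Of the 40 respiratory chain genes, 0 rose, 4 fell and 36 did not pass, with 0 and 3 adjusted over the list alone, 1 and 7 at unadjusted limma p under 0.05, and 1 and 0 at equal medians (camera adjusted p = 0.592). The fallen members NDUFA5, NDUFS6, NDUFV2 and NDUFA12 lost their calls at equal medians (adjusted p = 0.105, 0.0979, 0.0730 and 0.299). NDUFA12 also lost it without control library 1 (0.0529), control library 2 (0.0753), LPS library 1 (0.0577) or LPS library 2 (0.159), NDUFA5 without LPS library 1 (0.0516) and NDUFS6 without control library 2 (0.0512).

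The largest rise of any tested gene was that of avidin, a biotin-binding protein of egg white, from 8.80 ± 2.47 to 2289.8 ± 76.1 FPKM (log2 fold change 7.89, SE 0.21, limma adjusted p = 2.62e-06, SD, n = 2). Mitochondrial transcripts also held peaks, 21 in control over 11769 bases and 20 in LPS over 10060 bases, with median fold enrichments of 11.5 and 11.75 and the highest value at 93.7 in ND2 in control and at 69.2 in ND6 in LPS. These peaks ran from base 1740 to 16705 in control and from 2847 to 16705 in LPS. Coverage this broad does not place single m6A sites, and the non-specific antibody control was not analysed here.

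More genes fell than rose on the deposited scale. The genes that rose held 8.84% of all FPKM in control and 27.7% in LPS libraries, which alone lowers every other gene by a predicted −0.33 on the log2 scale (−0.35 to −0.32 over pairs of libraries), close to the observed median of −0.34. This share effect of FPKM is a candidate explanation for the excess of falls, and at equal medians 54.3% of calls were falls in place of 74.6%. A general loss of RNA from the other genes would look the same on this scale, and no spike-in was used here to part them.

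The LPS list held fewer peaks than the control list. Lower expression as the whole cause is argued against by genes whose scaled level moved by less than 0.25 on the log2 scale, where LPS peaks were still 0.787 of control peaks (exact 95% interval 0.740 to 0.836, for counting error only). Dilution by the risen transcripts as the whole cause is argued against in the same way by genes with stable FPKM, at 0.858 (0.801 to 0.918). Weaker peak calling after LPS may account for it, but the value examined cannot single it out. Of the control-only peaks, 63.9% (62.1 to 65.7%) lay in the least significant 33.3% of the control list, against 16.2% of shared control peaks. The median fold enrichment was 3.93 for control-only and 6.86 for shared control peaks. It was likewise 2.925 for LPS-only and 5.38 for shared LPS peaks, so unshared peaks were the weaker ones in either list. A general fall of m6A, which the treatment could bring, would leave the same mark and stays open, untested.

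Genes gained and lost called peaks with the direction of their expression, so expression change alone is a candidate explanation for the turnover. Stable expression here means a scaled level that moved by less than 0.25 on the log2 scale. Of tested genes with a peak, 29.9% gained or lost it, and 24.1% of those with stable expression, a ratio of 80.6% (bootstrap 95% interval 74.7 to 86.5%). The value lies above the 75% set beforehand, but its interval reaches just below it, so for the turnover as a whole the explanation cannot be told apart from a change in m6A or in calling. For lost peaks the ratio was 86.7% (79.6 to 93.7%), above that bound, which argues against a change of the scaled level alone as their cause. Genes with a stable scaled level could still hold a smaller share of the LPS reads. Lost peaks were not tested among genes with stable FPKM, so that share is not excluded as their cause. For gained peaks the ratio was 56.7% (43.9 to 70.3%), with 56 genes among those of stable expression, and its interval lay wholly below the 75% bound. Expression alone is thus not argued against for gained peaks, and a change in m6A or in calling is not excluded.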
